A study of Rattus norvegicus with 6 samples.

How the data were processed

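The series compared the pancreas of rats on a control diet with that of rats on an ethanol diet. Per the labels, 3 rats were used for each diet and each rat gave 1 array, so the replicates are separate animals. Per the labels' protocols, total RNA was taken from tissue lysate with a commercial column kit, and 5 micrograms were turned into biotin-labelled cRNA for hybridisation. The probe set names are those of a single-colour Affymetrix rat expression array, on which a gene is read by 1 or more probe sets.

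The values deposited by the authors are intensities, 1 per probe set and array. The scanner, the software and the normalization are not given in the sources used here, and what follows about the scale was read from the values. They are whole numbers on a linear scale. Background had been subtracted, since 931 to 949 of the values on each array lay below 0. The arrays had already been brought to nearly 1 distribution, with medians of 543 or 544. The largest difference between array medians on the log2 scale was 0.0024, under the limit of 0.2 that would have called for quantile normalization, so the values were used as deposited. A common distribution of this kind removes any difference in total RNA between diets. Present or absent calls were not used here, and neither were scanner files.

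Of 15923 probe sets, 57 hybridisation and labelling controls were left out, which left 15866. The platform annotation used for gene names is several years older than the reference. It gives 1 gene symbol for 12783 probe sets, several for 312 and none for 2771. No gene is named from a probe set with several symbols or none. Gene IDs were looked up in the RefSeq annotation of the GRCr8 rat assembly, which held 12748 of those with 1 symbol; no symbol changed through this step. No build is given for the array, so no coordinates are reported. Probe sets of near-identical genes, such as Hspa1a and its neighbouring copy, the amylases, the insulins, the globins and the Reg genes, can take up signal from each other, and their values are uncertain to that extent.

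Values below 0 were set to 0, a constant of 50 was added and the log2 was taken, so that fold changes are on the log2(value + 50) scale and understate the change of dim probe sets. Probe sets whose mean lay at or above the 40th percentile were tested, which kept 9520 probe sets of 7106 genes. The diets were compared with limma 3.58.1 in R 4.3.3, by a linear model with 2 groups and no block, moderated by empirical Bayes. P-values were adjusted by the Benjamini-Hochberg method over all tested probe sets, and an adjusted p under 0.05 was taken as a change. Log2 changes are given as ethanol minus control, with the standard error from limma. Group levels are means ± SD of the deposited intensities. The number of arrays limits the precision, and the median standard error of a log2 change was 0.18.

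For gene groups, each gene was represented by its kept probe set of highest mean. A gene of a list counts as measured if it had such a probe set, so genes below the intensity filter are not counted. The 16 pathway lists and 11 lists of cell type markers were fixed before the data were examined, as were the tests, their settings and the alternatives. A list was tested with camera of limma at a preset correlation of 0.01, with adjustment over the 16 pathway lists and over the 10 marker lists that had at least 3 measured genes. Beside it stand camera with a correlation estimated from the arrays, and fry, which asks whether the genes of a list move, on balance, one way or, in its mixed form, in either direction. Members of a list were also adjusted over the list alone.

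The genes to be named were set by a rule before the data were examined. It takes the 12 largest changes in each direction among genes, each read on its kept probe set of highest mean with 1 symbol, that passed and whose groups did not overlap, filled up by the smallest unadjusted p where fewer passed. It adds the 4 members of smallest p in each pathway list, the 2 members of highest mean in each marker list, and 15 genes set by name. Of those 15, Adh1, Hspa8 and Cckar had no probe set annotated to that gene alone. Genes named outside the rule are said to have been chosen after their values were seen.

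The alternatives were constants of 20 and 100, quantile normalization, equal medians, no filter, a filter at the 60th percentile, a variance trend, a replicate block, an adjusted p under 0.10, the mean of all probe sets of a gene, and each array left out in turn. The procedure was tested on simulated data with the 9520 probe sets and the spread of this comparison. In 10 simulations it recovered 63.7% of changes of 2-fold and 97.2% of changes of 4-fold, and 5.80% of its calls were false. A list of 35 genes shifted by 0.5 on the log2 scale was called in 10 of 10 simulations, and 2 unshifted lists were called over the 10 simulations. The simulated probe sets varied independently, unlike co-regulated genes, and their spread did not depend on intensity. Each simulation held 200 planted changes of 2-fold or 4-fold. In the data some larger changes did not pass, such as Ddit4 (log2 change 2.11) and Atf3 (3.66). Recovery may therefore be lower in the data, and a missing call does not show that a gene was unchanged.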

Results

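Gene expression was measured in the pancreas of 6 rats, 3 on a control diet and 3 on an ethanol diet, to ask how chronic ethanol consumption affects this organ. Each pancreas was hybridised to 1 array of 15866 probe sets. Across probe sets, which are not independent replicates, log2 values correlated with r from 0.925 to 0.944 between rats on the same diet and from 0.913 to 0.929 between rats on different diets. Signal at the 3' end over that at the 5' end, a measure of RNA integrity, was 1.80 ± 0.313 for beta-actin in control rats and 1.67 ± 0.122 in ethanol rats (SD, n = 3; two-sided exact permutation p = 0.6). For GAPDH the ratio was 1.81 ± 0.262 and 1.67 ± 0.175 (exact permutation p = 0.6). The 10 brightest probe sets took 6.71% ± 0.0435 of the signal in control rats and 6.85% ± 0.202 in ethanol rats (exact permutation p = 0.3). As the arrays had been brought to nearly 1 distribution, this share could show little difference between diets. After adjustment over these 3 measures each exact permutation p was 0.6, and 3 arrays against 3 cannot give a p below 0.1.

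Pancreas from the ethanol-fed rats held less transcript of a metallothionein and of a Reg protein, and more of a galectin, a kinase and a heat shock protein. Mt2A, which encodes a metal-binding metallothionein, fell from an intensity of 27314 ± 2836 in control rats to 6314 ± 750 in ethanol rats (SD, n = 3), a log2 change of -2.11 (SE 0.16, limma adjusted p = 0.00271). Reg3a, a secreted lectin of the Reg family, fell from 7958 ± 2705 to 1199 ± 757 (log2 change -2.80, SE 0.42, limma adjusted p = 0.0448). Lgals2, a galectin, rose from 145 ± 93.0 to 1041 ± 157 (log2 change 2.58, SE 0.31, limma adjusted p = 0.0287). Pim3, a serine/threonine kinase, rose from 2505 ± 347 to 8105 ± 630 (log2 change 1.68, SE 0.16, limma adjusted p = 0.00957). Hsph1, a large cytosolic heat shock protein, rose from 1531 ± 80.8 to 3312 ± 526 (log2 change 1.08, SE 0.16, limma adjusted p = 0.0448). The limma adjusted p of Hsph1 ran from 0.00595 to 0.194 over the alternatives.

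**Figure D1:**
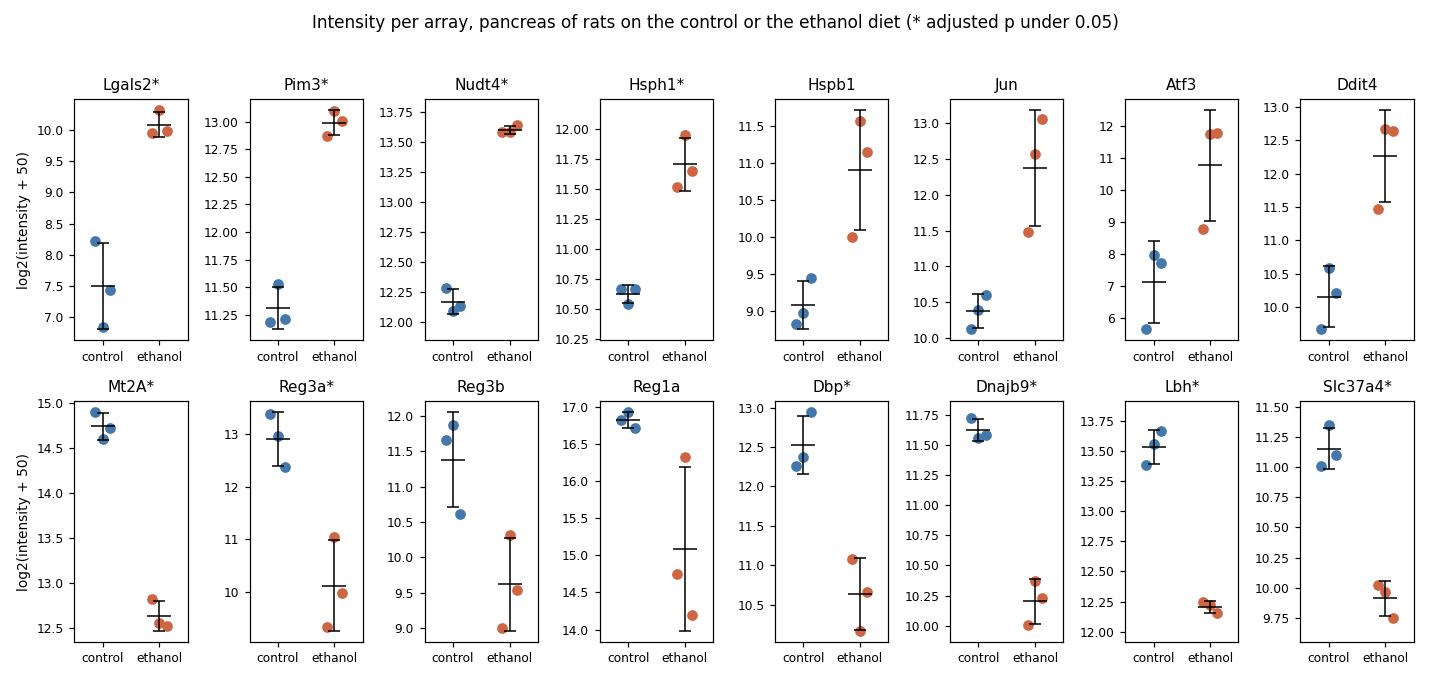
Each panel shows log2(intensity + 50) of 1 gene on the 3 control arrays (blue) and the 3 ethanol arrays (orange), with the mean and SD in black; axes differ between panels, and a star marks an adjusted p under 0.05. The groups of all starred genes are apart, as for Mt2A (log2 change -2.11) and Pim3 (1.68), while for Atf3 ethanol replicate 1 lies between the controls and the remaining ethanol arrays.

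Of the 9520 probe sets tested, 39 changed, 10 higher and 29 lower in ethanol. On all 39 the 3 ethanol arrays lay on the same side of the 3 control arrays, an arrangement seen on 25.4% of tested probe sets against 10% by chance. They comprised 32 probe sets of 1 gene, 2 annotated to several genes and 5 without a symbol. On the representative probe sets, 5 genes rose and 26 fell. At an unadjusted p under 0.05, 1747 probe sets differed, 769 higher and 978 lower, where chance gives 476. The count rested on the settings: limma called 0 probe sets without the intensity filter (2263 at an unadjusted p under 0.05), 12 with a constant of 20 (Mt2A, Pim3, Nudt4, Dnajb9, Lbh, Slc37a4, Ddhd2 and LOC102549726 among the genes the rule names), 134 with a filter at the 60th percentile and 249 with a variance trend. It was 3, 4 and 2 without control replicates 1, 2 and 3, and 38, 14 and 2 without ethanol replicates 1, 2 and 3; Mt2A and a probe set annotated to several genes passed in all 6 of these fits, and all 39 kept their sign.

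The remaining genes that rose were Ncoa3, a nuclear receptor coactivator, from 220 ± 117 to 841 ± 84.8 (log2 change 1.81, SE 0.28), and Nudt4, a diphosphoinositol polyphosphate phosphatase, from 4571 ± 336 to 12351 ± 280 (1.43, SE 0.13). Over the alternatives the limma adjusted p of Ncoa3 ran from 0.0166 to 0.197, and the change of Nudt4 was 0.80 when its 3 probe sets were averaged. The other 7 genes that the rule names as higher did not pass (limma adjusted p from 0.0571 to 0.0657). Their log2 changes were 2.11 (SE 0.35) for Ddit4, an inhibitor of mTORC1, 2.00 (SE 0.36) for Jun, 1.60 (SE 0.27) for 1810009J06Rikl, 0.85 (SE 0.15) for Tgoln2, 0.81 (SE 0.14) for the transcription factor Klf15, 0.78 (SE 0.14) for the ER-phagy receptor Retreg1 and 0.76 (SE 0.13) for Hapstr1.

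Among the genes that fell, Dbp, a transcription factor of the circadian output, went from 5986 ± 1607 to 1589 ± 504 (log2 change -1.90, SE 0.27, limma adjusted p = 0.0448). Dnajb9, a co-chaperone of the endoplasmic reticulum (ER), went from 3113 ± 202 to 1134 ± 151 (-1.42, SE 0.15, limma adjusted p = 0.0168). Lbh went from 11863 ± 1158 to 4675 ± 157 (-1.33, SE 0.14), and Slc37a4, the glucose 6-phosphate transporter of the ER, from 2244 ± 284 to 916 ± 94.5 (-1.25, SE 0.16). LOC102549726 (-1.33), the mitochondrial ribosomal protein mrpl9 (-1.33), the sulfhydryl oxidase Gfer (-1.31), Frmd8 (-1.31), the phospholipase Ddhd2 (-1.29) and the ubiquitin ligase Rnf138 (-1.29) also fell, with standard errors from 0.15 to 0.21.

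Outside the rule, and chosen after their values were seen, the zinc transporter Slc30a2 (-1.12, SE 0.17), the keratin Krt18 (-1.11, SE 0.15), the vesicle priming factor Cadps (-1.19, SE 0.18), the desmosomal cadherin Dsc2 (-1.08, SE 0.14), the kinase Wee1 (-0.95, SE 0.14) and the Golgi protein Golgb1 (-0.94, SE 0.14) also fell. So did a probe set annotated to several genes, the same that passed with each array left out (58072 ± 3757 to 10248 ± 2053, log2 change -2.51, SE 0.18). Likewise chosen after its values were seen, the other probe set annotated to several genes rose from 580 ± 117 to 3742 ± 1818 (2.46, SE 0.38).

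Digestive enzyme transcripts, the main products of acinar cells, had a median log2 change of 0.038 over 20 measured genes (camera adjusted p = 0.790). This does not show that they were stable: 11 of the 20 read at 80% or more of the lowest array maximum (maxima from 163449 to 171742), where saturation can hide a change. The other 9 had a median of 0.07. This check was chosen after the values were seen. Amy1, an amylase, fell from 11423 ± 1046 to 6115 ± 538 (log2 change -0.90, SE 0.15) when adjusted over the list alone (limma adjusted p = 0.00474) but not over all genes tested (limma adjusted p = 0.0524), and the other 19 did not pass. The brighter amylase Amy2a3 was at 81793 ± 9519 and 85674 ± 3310 (0.07, SE 0.15). The lipase Cel, at -0.03 (SE 0.13), lay at the top of the range (162192 ± 1552 and 159310 ± 3814), so its change is not known. Log2 changes were 0.20 (SE 0.14) for the trypsinogen Prss2, 0.07 (SE 0.18) for the trypsin inhibitor Spink1, 0.24 (SE 0.14) for Spink1l and 0.19 (SE 0.16) for the zymogen granule protein Cuzd1. None of the 30 genes of zymogen granules and secretion passed either adjustment by limma, with 3 higher and 2 lower at an unadjusted p under 0.05 (list median -0.0072, camera adjusted p = 0.861). Its members of smallest p were Snap23 (0.57, another probe set 0.25), Rab3d (-0.62), Rab27b (-0.48) and Scamp1 (0.36), and another probe set of Scamp1 had the opposite sign (-0.07).

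Heat shock proteins went in both directions. The list holds cytosolic chaperones and their partners, the mitochondrial chaperones Hspa9, Hspd1 and Hspe1, and the factors Hsf1 and Hsf2. Of 17 measured genes, Hsph1 passed over all genes tested and 8 passed when adjusted over the list alone, 5 higher and 3 lower. Hspb1, a small heat shock protein, rose by that adjustment from 501 ± 129 to 2049 ± 1008 (log2 change 1.82, SE 0.37, adjusted p over all genes 0.0858). Dnaja2 (-0.70, SE 0.14) and Hspb6 (-0.76, SE 0.18) fell by it. Chosen after their values were seen, Hspa1a (2.24, SE 0.55), Dnajb1 (1.56, SE 0.41) and Dnaja1 (0.58, SE 0.14) rose over the list alone, and St13 (-0.69, SE 0.21) fell. The list as a whole had a median of 0.11 and was not shifted (camera adjusted p = 0.367).

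Immediate early and stress transcription factors were higher as a list, with a median log2 change of 0.26 over 27 genes, 22 of them positive (camera adjusted p = 0.00281). The call was lost with an estimated correlation (adjusted p = 0.971, unadjusted p = 0.0726) and without ethanol replicate 3 (median 0.20, adjusted p = 0.0799). With a filter at the 60th percentile the median was 0.54 over 19 genes, and over all alternatives the adjusted p ran from 6.29e-06 to 0.971. No member passed over all genes tested with limma, and 7 were higher and 1 lower at an unadjusted p under 0.05. Adjusted over the list alone, 5 rose and 22 did not pass. The risers were Jun (2.00, SE 0.36), Klf9 (0.78, SE 0.17), Atf3 (3.66, SE 0.87), Per1 (0.69, SE 0.17) and, chosen after its values were seen, Klf6 (1.37, SE 0.35). For Klf9 the other probe sets gave 0.08 and 0.58, and the mean of its probe sets 0.48. Atf3, a factor induced by many stresses, was at 108 ± 128 in control rats, with control replicate 1 below 0, and at 388, 3413 and 3459 in ethanol replicates 1, 2 and 3. Egr1 was at 1316 ± 105 in control rats and 2325 ± 1487 in ethanol rats (0.54, SE 0.48). Its ethanol replicates 1, 2 and 3 were at 768, 3731 and 2475, replicate 1 below all 3 controls and the others above them. On the same arrays the erythroid markers had a list median of 0.61, a call likewise lost with an estimated correlation (adjusted p = 0.339).

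Among 31 ER chaperones and genes of the unfolded protein response, Dnajb9 fell over all genes tested and over the list alone, and 30 did not pass (list median -0.094, camera adjusted p = 0.834). At an unadjusted limma p under 0.05, 5 of the 31 were higher and 7 lower, so a median near 0 does not show an unchanged list. Log2 changes were -0.32 (SE 0.14) for the chaperone Hspa5, -0.50 (SE 0.15) for the transcription factor Xbp1, 0.68 (SE 0.18) for Erp29 and 0.57 (SE 0.18) for Sdf2l1.

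In the list of pancreatitis-associated and acute phase genes, 3 Reg genes fell. They were the members of the 14 measured that passed over the list alone, and of them Reg3a passed over all genes as well. Reg3b went from 2795 ± 1132 to 791 ± 387 (log2 change -1.76, SE 0.40), and Reg1a from 116005 ± 8312 to 42583 ± 34095 (-1.74, SE 0.46). The remaining Reg gene of the list that was measured, Reg3g, did not pass: chosen after its values were seen, it was at 482 ± 244 and 584 ± 105 (0.36, SE 0.34). Over the alternatives the limma adjusted p of Reg3a ran from 0.00539 to 0.197. Cd44, a cell surface receptor, was at 0.34 (SE 0.14) on its brighter probe set and 0.93 (SE 0.24) on the other, and passed on neither. The list's median was 0.050 while its mean was -0.33, and camera did not call it (adjusted p = 0.790).

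Antioxidant and glutathione genes split in direction: adjusted over the list alone, 2 of 34 rose and 4 fell, and Mt2A alone passed over all genes. The glutathione peroxidase Gpx1 rose by that adjustment from 9535 ± 866 to 15026 ± 1060 (log2 change 0.66, SE 0.14), as did the mitochondrial thioredoxin reductase Txnrd2 (1.12, SE 0.30). The haem oxygenase Hmox2 (-0.61, SE 0.17), the glutathione transferase Gstm1 (-0.60, SE 0.17) and, chosen after its values were seen, Prdx6 (-0.77) fell by it. The list had a median of -0.10 (camera adjusted p = 0.790).

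Genes of alcohol and aldehyde oxidation were not called: limma passed 0 of 19 over all genes or over the list alone, with 1 higher and 3 lower at an unadjusted p under 0.05 (list median -0.014, camera adjusted p = 0.861). Cyp2e1, an ethanol-oxidising cytochrome, was at 387 ± 108 in control rats and 448 ± 36.7 in ethanol rats (log2 change 0.22, 95% interval -0.25 to 0.69). The aldehyde dehydrogenase Aldh2 was at 2041 ± 250 and 2287 ± 34.7 (0.17, SE 0.15). The members of smallest p were Acss1 (-0.59), Adh5 (-0.39), Aldh9a1 (-0.58) and Aldh4a1 (0.36).

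Amino acid synthesis and transport held 4 genes that rose and 1 that fell of 34 when adjusted over the list alone, and 0 over all genes with limma (5 higher and 3 lower at an unadjusted p under 0.05). The glutamine transporter Slc38a2 (log2 change 0.86, SE 0.18), the cystathionine lyase Cth (0.66, SE 0.14) and the serine synthesis enzyme Psph (0.84, SE 0.20) rose by that adjustment, and the transaminase Gpt (-0.81, SE 0.19) fell. Chosen after its values were seen, Aldh18a1 (0.50) also rose over the list alone. The list had a median of 0.018 (camera adjusted p = 0.746).

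No member passed either adjustment by limma in the lists of fatty acid oxidation (38 genes, 6 higher and 6 lower at an unadjusted p under 0.05), sterol and fatty acid synthesis (25 genes, 3 and 4), oxidative phosphorylation (52 genes, 3 and 5), and extracellular matrix and stellate cells (35 genes, 2 and 0). Their medians were -0.049, 0.016, 0.042 and 0.074, with camera adjusted p of 0.958, 0.861, 0.834 and 0.367. The fatty acid oxidation genes of smallest p included Acot7 (-0.52), Crat (0.46), Pdk2 (0.52) and Ucp2 (-0.68). Those of lipid synthesis were Insig1 (0.73), Pmvk (-0.78), Elovl6 (0.44) and Acaca (0.42, another probe set 0.15). For oxidative phosphorylation they were Slc25a3 (-0.50), Ndufa4 (0.40), Vdac2 (-0.34) and Vdac1 (-0.49). A dimmer probe set of Vdac1, which does not represent it in the list, fell (-1.27, SE 0.19). That probe set passed over all probe sets tested (limma adjusted p = 0.0448). Matrix genes were Col5a1 (0.67), Col12a1 (0.47), Bgn (0.40) and Col18a1 (0.35), and another probe set of Col18a1 had the opposite sign (-0.35). In the lysosome list of 32 genes, Sqstm1, an autophagy receptor, fell over the list alone (-0.79, SE 0.15), while a dimmer probe set of it was at 0.06 and the mean of its probe sets at -0.50. Ctsc (0.58), Igf2r (0.42, another probe set 0.20) and Atp6ap1 (0.33) did not pass, and the list had a median of -0.015 (camera adjusted p = 0.861).

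Proteasome subunits were slightly lower as a list, with a median log2 change of -0.18 over 39 genes, 31 of them negative (camera adjusted p = 0.0240). The call was lost with an estimated correlation (adjusted p = 0.971, unadjusted p = 0.261), with a filter at the 60th percentile (adjusted p = 0.0548) and without control replicate 1, ethanol replicate 1 or ethanol replicate 3 (adjusted p of 0.103, 0.0948 and 0.180). Over all alternatives the adjusted p ran from 0.00380 to 0.971. No member passed either adjustment by limma, with 0 higher and 5 lower at an unadjusted p under 0.05. Psmf1 (-0.60, SE 0.20), Psmg3 (-0.57, SE 0.19), Psmd6 (-0.45, SE 0.14) and Psmd5 (-0.40, SE 0.13) had the smallest p. Of these, Psmf1 is a regulator and Psmg3 and Psmd5 are assembly factors rather than subunits. Ribosomal proteins had a median of -0.12, with 34 of 41 genes negative, and did not pass (camera adjusted p = 0.241). None of these 41 passed limma's test (1 higher and 2 lower at an unadjusted p under 0.05), among them Rps15a (-0.44), Rps3 (-0.38), Rps27l (0.74) and Rpl39 (0.25).

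**Figure D2:**
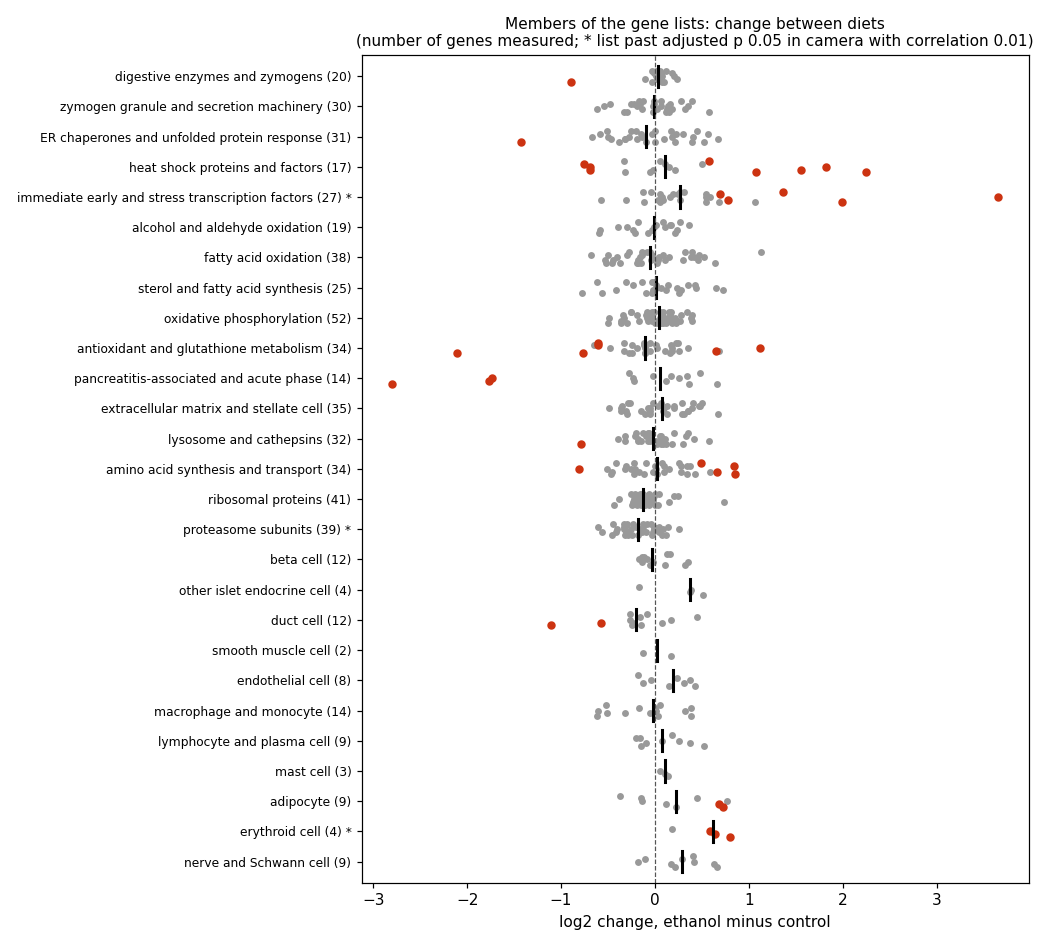
Each point is the log2 change of 1 gene between diets, ethanol minus control, in the list named on the left with its number of measured genes. Red points passed when adjusted over the list alone, black bars are list medians, and a star marks the 3 lists called by camera at a correlation of 0.01, with medians of 0.26, -0.18 and 0.61; with an estimated correlation none was called.

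Among markers of other cell types in the tissue, camera called the erythroid list higher at a correlation of 0.01, with a median log2 change of 0.61 over 4 measured genes (adjusted p = 0.0249). The call was lost with an estimated correlation (adjusted p = 0.339, unadjusted p = 0.136). Adjusted over the list alone, 3 of the 4 rose. Hbb, a globin, went from 12799 ± 2828 to 22200 ± 3102 (0.80, SE 0.20) and Hba-a3 from 3492 ± 866 to 5413 ± 730 (0.64, SE 0.20). The list call was also lost without the filter (median 0.38 over 7 genes, adjusted p = 0.0628) and without control replicates 1 and 2 (adjusted p of 0.0993 and 0.0552) or ethanol replicates 2 and 3 (0.0768 and 0.0546). Over all alternatives the adjusted p ran from 0.00201 to 0.339. Adipocyte markers had a median of 0.23 over 9 genes (camera adjusted p = 0.0857), with Lpl at 0.77 (SE 0.28) and Adipor2 at 0.23 (SE 0.15). Chosen after their values were seen, Pck1 (0.73) and Cfd (0.69) rose over that list alone. Duct cell markers had a median of -0.20 over 12 genes (camera adjusted p = 0.118) and passed by fry after adjustment, with Krt18 lower over all genes and Krt8 (-0.58), also chosen after its values were seen, over the list alone. Epcam (-0.25, SE 0.17) and Muc1 (-0.27, SE 0.13) did not pass.

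In the other marker lists no gene passed either adjustment by limma; at an unadjusted p under 0.05 there were 3 lower macrophage and monocyte genes and 1 higher lymphocyte gene, and 0 in the rest. Beta cells had a median of -0.035 over 12 genes (camera adjusted p = 0.699), with log2 changes of -0.17 (SE 0.20) for Ins1 and -0.09 (SE 0.19) for Ins2. Other islet cells had a median of 0.38 over 4 genes (adjusted p = 0.366), with Gcg at 0.38 (SE 0.44) and Sst at 0.52 (SE 0.32). Endothelial markers had a median of 0.19 over 8 genes (adjusted p = 0.348), with Plvap at 0.43 and Esam at 0.24. Macrophage and monocyte markers had a median of -0.021 over 14 genes (adjusted p = 0.488), with Aif1 at 0.39 and Lyz2 at 0.017. Lymphocyte and plasma cell markers had a median of 0.075 over 9 genes (adjusted p = 0.380), with Thy1 at 0.52 and Cd24 at -0.15 (SE 0.43). Nerve and Schwann cell markers had a median of 0.29 over 9 genes (adjusted p = 0.0857), with Gfap at 0.41 and Npy at 0.29. Mast cell markers had a median of 0.10 over 3 genes (adjusted p = 0.575), with Cpa3 at 0.14 and Tpsb2 at 0.06. Of 10 smooth muscle genes on the array, 2 had a probe set above the intensity filter, and the list was not tested. Myl9 was at 0.17 and Myh11 at -0.12.

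Across lists, fry found 3 of 16 pathway lists and 4 of 10 marker lists at an unadjusted p under 0.05, and 0 and 1 after adjustment. The 1 was the list of duct cell markers, whose transcripts were lower on balance. Camera did not call that list (adjusted p = 0.118), and lower transcripts do not measure the number of duct cells. The arrays read whole tissue, so which cells held these transcripts, Krt18 and Krt8 among them, was not tested. The call is therefore not one about duct cells as such. In the mixed form of fry, which asks for change in either direction, 15 pathway lists and 2 marker lists passed after adjustment. This form tests a list against no change, not against the other genes. Over all 9520 probe sets, 1747 had an unadjusted limma p under 0.05 where chance gives 476. Passing therefore does not set these lists apart from the other genes. The sign of camera differed from that of the median in the lists of zymogen granules, fatty acid oxidation, lysosome, pancreatitis and beta cells, none of which camera called. The mean took the sign of the median in the lists of zymogen granules, fatty acid oxidation and lysosome, and the sign of camera in those of pancreatitis and beta cells.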

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

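The alternatives and the arrays left out in turn were all chosen before the data were examined. For the 113 genes named by the rule, 1492 of 1681 values under alternatives kept their direction and their side of the threshold, 113 lost the call, 63 gained it and 13 changed sign, the last all with 1 array left out. The count of 1747 probe sets at an unadjusted p under 0.05 stayed within 1.5 times under each alternative, from 1236 to 2263. These counts are not all over the same number of tests. Limma gave 1747 of 9520, 2263 of 15866 without a filter and 1409 of 6347 with a filter at the 60th percentile. The share thus rose with a stricter filter. The count of 39 changed probe sets became 12 with a constant of 20, 134 (48 higher, 86 lower) with a filter at the 60th percentile, 249 (88 higher, 161 lower) with a variance trend and 228 (83 higher, 145 lower) at an adjusted p under 0.10. Of the 39, 38 were among those called with the variance trend, and 25 were kept and called at the 60th percentile. Without a filter limma called 0 (2263 at an unadjusted p under 0.05), with a lowest adjusted p of 0.0701. The number of probe sets tested then rose to 15866, but this was not the only change. The unadjusted limma p of Mt2A also rose, from 5.69e-07 to 1.31e-05. Constants of 100, quantile normalization and equal medians gave 56, 42 and 39. With 1 array left out the count ran from 2 to 38. It was 3, 4 and 2 without control replicates 1, 2 and 3, and 38, 14 and 2 without ethanol replicates 1, 2 and 3. Each of these fits had the same number of arrays, so that number does not account for the range. Of the 38 without ethanol replicate 1, 21 were among the 39. That array had the largest SD of log2 deviations from the group mean, 0.405 against 0.349 to 0.381 for the other arrays. Whether this accounts for the 38 was not tested. Where nothing is said of the construction of an alternative, the cause was not tested.

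Replicate numbers showed no sign of pairing in the values: the deviations of same-numbered arrays from their group means correlated at -0.030, 0.026 and -0.14. This does not show that the rats were unmatched, and the sources used here do not say whether the numbers pair them. With the replicate block 6 probe sets were called, 3 of them shared with the 39.

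The 2 pathway lists called by camera became 3 with a variance trend (1 higher, 2 lower) and 1 with a filter at the 60th percentile. They became 0 with an estimated correlation and 0 to 2 with 1 array left out, where the 0 was without ethanol replicate 3 (3 lists at an unadjusted p under 0.05). The 1 marker list became 0 without a filter (3 unadjusted), 0 with an estimated correlation, and 0 to 2 with 1 array left out. It was 0 without control replicates 1 and 2 and ethanol replicates 2 and 3 (4, 3, 3 and 4 unadjusted). With an estimated correlation camera had 0 lists of either kind at an unadjusted p under 0.05.

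Genes whose log2 change took either sign with 1 array left out, none of which passed, were Lyz2 (-0.10 to 0.15), Cd24 (-0.59 to 0.36), Cyp2e1 (-0.0028 to 0.35), Spink1 (-0.057 to 0.20), Tpsb2 (-0.041 to 0.15), Ins1 (-0.27 to 0.017), Ins2 (-0.22 to 0.11) and Gcg (-0.059 to 0.93). Signal near background limits Lgals2, Ncoa3 and Atf3, whose controls lay at 145, 220 and 108; with a constant of 100 their changes were 2.28, 1.61 and 3.20. With a constant of 20 Lgals2 lay below the filter and was not tested, and Ncoa3 did not pass (limma adjusted p = 0.0632). Neither was kept by the filter at the 60th percentile.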

Other observations

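The tests of handling at collection and of RNA degradation, and the counts of splits for probe sets, were chosen only after the results were seen. So was the clock test in part: Per1 was known to be higher when it was written, and it was widened to dimmer genes after its first value was seen. The other tests were written before the values they measure were looked at, though after the genes that prompted them; for Glul, Cpt1a and Gadd45a it was already known that they were not among the leading changes of their lists. Clock genes went different ways, none besides Dbp and Wee1 past the threshold over all genes. Bhlhe41 was at 1295 ± 698 in control rats and 423 ± 52.7 in ethanol rats (log2 change -1.40, SE 0.31), and Nr1d1 at 680 ± 534 and 2056 ± 1143 (1.57, SE 0.57), with overlapping groups. Per2 was at 4418 ± 321 and 2971 ± 2197 (-0.79, SE 0.41), also overlapping, and Tef (-0.0015), Nr1d2 (0.06), Bhlhe40 (-0.04) and Clock (0.13) lay near 0. Of genes known to respond to glucocorticoids, none of the following passed: Errfi1 (1.36, SE 0.45) and Pdk4 (1.13, SE 0.37), both with overlapping groups, Tsc22d3 (0.68, SE 0.15) and Cdkn1a (0.61, SE 0.15), with groups apart, and Angptl4 (0.33), Lpin1 (0.21), Fkbp5 (0.17), Sult1a1 (0.09) and Glul (-0.22), all overlapping. Sesn1, a stress-induced sestrin, was at 1053 ± 287 and 2099 ± 156 (0.99, SE 0.20). All these genes were chosen after the comparison was seen.

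A different circadian phase in the groups may lower Dbp. The first form of the test used genes above the intensity filter. Clock, the 1 gene of opposite phase, lay 0.12 above the mean of 7 genes assigned to the phase of Dbp (log2 scale). The SE over genes was 0.95 and the exact permutation p was 0.625. With 1 gene against 7, the permutation has too few arrangements for its p to call a shift. The difference of 0.12 is under the limit of 0.25 set against a phase shift, but by less than its spread. The 7 genes also go both ways, and whether they share the phase of Dbp in these rats was not tested. The difference therefore does not speak against a shift. The test was widened to genes below the filter only after that value was seen, and gave 0.39 over 3 and 9 genes (exact permutation p = 0.445), under the 0.5 set for a shift. Of the 7, Per1 and Nr1d1 lay higher and Bhlhe41 and Per2 lower in ethanol, none past the threshold over all genes, and the groups overlapped for Nr1d1 and Per2. The arrays leave the question open, and the time of day of collection is not given in the sources used here.

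Lower zinc-dependent transcription may link Mt2A and the zinc transporter Slc30a2. The test was Slc30a1, another zinc-induced gene, which lay below the intensity filter at 333 ± 92.4 in control rats and 201 ± 169 in ethanol rats. Its log2 change was -0.87 with a 95% interval from -2.42 to 0.69, which decides nothing. Of genes expected to be higher with low zinc, Slc39a4 was at 0.44 (SE 0.24), with overlapping groups, and Slc39a10, below the filter, at 0.11.

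For Klf15, Ddit4, Klf9, Per1 and Pdk4, a stronger glucocorticoid signal and a lower insulin signal were compared as hypotheses. The 8 other measured glucocorticoid-induced genes had a median log2 change of 0.27, at percentile 98.96 of 10000 random lists matched on expression, as a stronger glucocorticoid signal would give. Left out of it were 5 measured genes of this kind whose values had been seen, among them Mt2A, which fell; with these, a set chosen afterwards, the median was 0.33 over 13 genes. Klf9 itself was at 0.48 when its probe sets were averaged. The 7 measured genes that fasting or FOXO factors induce had a median of 0.17, at percentile 91.88, between the limits set in advance. A list of 6 fast-responding genes, weighed below, reached percentile 99.99 of such random lists. A high percentile is therefore not particular to glucocorticoid-induced genes. Random lists ignore that co-regulated genes move together from rat to rat, so a chance difference between these 6 rats is not ruled out, and the diet itself was not separated from stress at collection. Time of day and pair-feeding, which both bear on these genes, are not given in the sources used here.

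Higher heat shock and immediate early genes in ethanol were weighed against 3 technical explanations, using the 10 members that rose over their list alone. A single ethanol animal was not ruled out by its test: the mean log2 change of 1.58 kept at least 87.8% of its size without any 1 ethanol array (1.94, 1.38 and 1.41 without ethanol replicates 1, 2 and 3). All 10 had been picked for passing on these same arrays and had their groups apart. This favours that outcome beforehand without fixing it, so the test does not decide. The median of the whole immediate early list, 0.26 over all arrays, was 0.31, 0.29 and 0.20 without ethanol replicates 1, 2 and 3. Its call was lost without replicate 3 (camera adjusted p = 0.0799), which does not point to that animal alone, as most of the median stayed. Slower handling of the ethanol tissue at collection stays open. Its 6 fast-responding genes had a median of 0.54, at percentile 99.99 of random lists, with 0 of them at an unadjusted limma p under 0.05. They all belong to the immediate early list that was already called, so this restates the pattern and lends handling no support of its own. More degraded RNA was not shown and not ruled out: the log2 3' over 5' ratio differed by -0.10, with an upper 95% bound of 0.27. A response to the ethanol diet in the living animal remains open and untested, since it would raise the same genes as handling.

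Splits of the 6 arrays into 3 and 3 number 10, too few for a share under 0.05. The real split gave 39 changed probe sets and the highest other split 1, so that 1 split of 10 gave as many. At an unadjusted p under 0.05 the real split gave 1747 and the highest other split 514, again 1 split of 10. For pathway lists the real split gave 2 and the highest other split 2, with 5 of 10 splits giving as many. For marker lists the real split gave 1 and the highest other split 2, with 5 of 10 splits giving as many.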
